A study of Botryosphaeria dothidea with 3 samples.

How the data were processed

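RNA was sequenced from mycelium of Botryosphaeria dothidea, a filamentous fungus that causes canker and fruit rot of woody plants, grown at 25 °C or held at 35 °C for 1 h or for 6 h. There were 3 libraries, 1 per condition, and each was placed in its group by the temperature and time in its label. Total RNA was extracted with a phenol-based reagent and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name TopHat2, a spliced read aligner, and Cufflinks, which estimates transcript abundance, with no version or settings. The genome build, the gene annotation, the library's strandedness and any pooling of cultures are not given in the sources used here.

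The deposited table holds FPKM values (fragments per kilobase of transcript and 1000000 mapped fragments), as the column names in the file header state, with 1 column per condition. Each column was matched to a library by its temperature and time, which only 1 library carries, and 0 other columns of values were present. FPKM are scaled by the authors to each library's mapped fragments and to gene length, so they are relative amounts: a change in a few abundant genes alters the values of all others, and a value says nothing of RNA per cell. The table has 14885 rows and 14859 distinct IDs. In it 25 IDs stand on more than 1 row (51 rows), with different values. Rows were kept as separate genes, those 51 were never named individually, and leaving them out was tried as an alternative. An FPKM of 0 can be a failed estimate as well as a gene without reads, so genes are described as listed at 0.

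The table pairs no ID with a gene name, and no annotation of this organism was used here. The 36 gene lists fixed before the data were examined (chaperones, proteasome, ribosome, antioxidants, cell wall and others) were searched for in the IDs and matched 0 of them, so they gave no result and pathways are not analysed here. Under the rule for named genes fixed at the same time, IDs without names are limited to the 2 highest and the 2 lowest differences per comparison among genes that reach FPKM 10 in the higher of both libraries.

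The comparisons were 1 h over 25 °C, 6 h over 25 °C and 6 h over 1 h. Values were put on the scale log2(FPKM + 1), so the pseudocount was 1. Genes were kept where FPKM reached 1 in at least 1 library, which left 11571 rows and removed 3314. A gene counted as higher or lower at a 2-fold difference on that scale, which understates the change of weak genes, and 4-fold was the stricter step. With 1 library per condition there is no replicate error, so no test between conditions was made and no p-value is given. Each count describes these libraries. The spread across genes, as a robust SD (scaled median absolute deviation), was used as a yardstick. Genes were grouped by level as their mean log2(FPKM + 1) over the 3 libraries, with edges at 2, 4, 6 and 8 (FPKM of about 3, 15, 63 and 255). For overlaps of 2 comparisons that share a library, 100 sets of 3 unchanged libraries were simulated, with noise drawn per level from the differences between 1 h and 25 °C with random sign. That noise includes any real response at 1 h and is therefore wide, but it does not carry the wider spread and the shift of the 6 h library. A second set of 100, chosen after seeing the data, gave the 6 h library its own observed spread and level medians, which include any real response at 6 h.

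The number of fragments per library is unknown from FPKM, so no counting interval or detection limit is given. Relative depth could be read from weak genes, because 1 fragment is worth an FPKM inversely proportional to depth. Among genes listed above 0 and under FPKM 0.6 in both libraries, the commonest ratio was 1.04 for 1 h over 25 °C (478 genes), 1.03 for 6 h over 25 °C (392 genes) and 0.986 for 6 h over 1 h (408 genes). Of these genes 71.8%, 68.4% and 81.1% had ratios within 5% of that value times a ratio of small whole numbers, against 20.7%, 22.6% and 17.4% at random offsets. The commonest ratio was picked from the same genes, which favours its share over that at random offsets, so these shares are not like measures. Read from the commonest ratios, the libraries were of nearly equal depth.

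Alternatives were a pseudocount of 0.1 or 5, no filter or a filter at FPKM 5, median-ratio, upper-quartile or column-total scaling, and the 4-fold step. Quantile normalization and leaving out rows that share an ID were chosen after seeing the data. Upper-quartile and column-total scaling were planned only for the counts of higher and lower genes per comparison, not for shared genes or groups by step. Recomputing median differences and gaps between levels was not planned either. The measuring code was tested on simulated data built from the 25 °C column for the comparison of 1 h with 25 °C (14885 rows, 200 seeded genes). All seeded genes had FPKM of 10 or more at 25 °C. The noise had the same width at every level, set from the robust SD of 0.49 at 1 h, against 0.64 in genes of mean log2(FPKM + 1) under 2. The shares recovered therefore cover stronger genes only, and the unchanged genes passing do not estimate false calls in these libraries. At a seeded 4-fold difference, 99% of the genes made higher and 94% of those made lower passed the 2-fold step, and 302 unchanged genes also passed it. At a seeded 2.5-fold difference the shares were 76% and 67%, with 323 unchanged genes passing. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.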

Results

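To follow the response of B. dothidea mycelium to heat, transcript abundance was measured in 1 library at 25 °C, 1 library after 1 h at 35 °C and 1 library after 6 h at 35 °C. No condition has a second library here, so none of the differences has a replicate check, and each describes these libraries. The library titles end in 3 at 25 °C and at 1 h, but in 1 at 6 h. What these endings mean, and whether further libraries were made, is not given. If they mark cultures or batches, such a difference cannot be told apart from the time at 35 °C. Each column of the table was taken as 1 library; whether a column is a mean over several cultures or libraries is not given in the sources used here. FPKM were listed for 14885 genes. The number at FPKM 1 or more was 10704 at 25 °C, 10744 at 1 h and 11149 at 6 h. The number listed at 0 was 2542, 2541 and 2302 in the same order, and 1689 genes were listed at 0 in all 3 libraries. The median FPKM over all genes was 9.89 at 25 °C, 10.5 at 1 h and 13.8 at 6 h. The 100 strongest genes of each library held 28.1% of summed FPKM at 25 °C, 25.0% at 1 h and 23.95% at 6 h. The fragments behind these values are unknown, but the steps between weak values placed the depths of the 3 libraries within about 5% of each other.

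The first comparison asked what differed after 1 h at 35 °C. Among genes reaching FPKM 10 in the higher library, the one furthest above its 25 °C level was Botdo_05614, at FPKM 3.31 at 25 °C and 56.0 at 1 h, a difference of 3.72 on the log2(FPKM + 1) scale. Botdo_14320 followed, at 282.5 and 1992, a difference of 2.81. In the other direction, the largest differences among such genes were those of Botdo_10019, at 52.7 at 25 °C and 3.62 at 1 h (-3.54), and Botdo_10048, at 116.7 and 9.17 (-3.53). Of 11571 genes kept, 457 (3.95%) were at least 2-fold higher and 417 (3.60%) at least 2-fold lower, while 10697 (92.4%) stayed within 2-fold. At the 4-fold step 36 genes were higher and 49 lower. No gene went from a listed 0 to FPKM 10 or more, or the reverse.

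Most genes lay close to their 25 °C level at 1 h: the median difference was 0.06 and the robust SD across genes 0.49 (log2). Genes of mean log2(FPKM + 1) under 2 passed the 2-fold step most often, with 8.40% higher and 7.72% lower, and their robust SD was 0.64. Among genes between 4 and 6 the shares were 2.37% and 1.73%, with a robust SD of 0.43. The most abundant genes lay together below their 25 °C level. For the 131 genes with a mean of 10 or more (FPKM of about 1023), the median difference at 1 h was -0.51, 102 of the 131 lay below their 25 °C value and 81 lay within 0.25 of the group's median. That median stayed below 0 under each scaling tried, from -0.60 with upper-quartile scaling to -0.15 with quantile normalization. The 482 genes between 8 and 10 had a median of 0.00064, with 241 below their 25 °C value. Without replicates, the share of the 874 genes past 2-fold that reflects sampling is open.

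**Figure D1:**
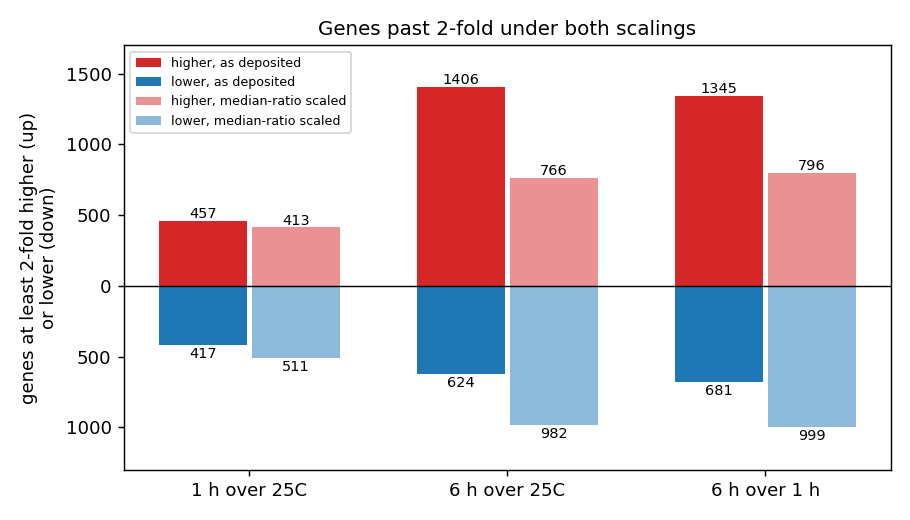
Bars give the number of genes at least 2-fold higher (upward) or lower (downward) in each of the 3 comparisons, on log2(FPKM + 1), for FPKM as deposited (dark) and after median-ratio scaling (light). As deposited, 1406 genes were higher and 624 lower at 6 h than at 25 °C; after scaling, 766 were higher and 982 lower.

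After 6 h at 35 °C more genes stood apart from 25 °C than after 1 h. Botdo_15892 had FPKM 1.38 at 25 °C, 7.51 at 1 h and 296.7 at 6 h, a difference of 6.97 between 6 h and 25 °C on the log2(FPKM + 1) scale. Botdo_15898 had 0.164, 1.53 and 70.7, a difference of 5.95. At the other end, Botdo_13411 had 249.4 at 25 °C, 206.0 at 1 h and 5.08 at 6 h (-5.36), and Botdo_12453 had 2238, 881.7 and 68.3 (-5.01). At least 2-fold higher were 1406 genes (12.2% of 11571) and at least 2-fold lower were 624 (5.39%). At the 4-fold step the numbers were 132 and 129. From a listed 0 at 25 °C, 150 genes reached FPKM 1 or more at 6 h, of which 3 reached 10 or more. In the other direction 72 genes went from FPKM 1 or more to a listed 0, of which 1 had stood at 10 or more.

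The excess of higher genes at 6 h depended on how the libraries were scaled. The median difference of all kept genes was 0.30 (log2), and 69.3% of the genes past 2-fold were higher. Relative to that shift, after median-ratio scaling, 766 genes were higher and 982 lower, so that 43.8% of those past 2-fold were higher. With upper-quartile scaling the numbers were 992 and 808 (55.1% higher), and with quantile normalization 699 and 941 (42.6%). Scaling to the column total gave 1823 and 546 (77.0% higher). At 1 h the share of higher genes was 52.3% as deposited and 44.7% after median-ratio scaling.

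The direction at 6 h varied with expression level. As deposited, genes of mean log2(FPKM + 1) under 2 had a median difference of 0.44 from 25 °C, those from 2 to 4 one of 0.49, those from 4 to 6 one of 0.37, those from 6 to 8 one of 0.07 and those of 8 or more one of -0.28. In the group from 2 to 4, 532 of 2690 genes were at least 2-fold higher and 122 at least 2-fold lower. In the group of 8 or more, 21 of 613 were higher and 69 lower. The gap between the medians of these groups was 0.77 at 6 h against 0.15 at 1 h, 0.81 at 6 h after median-ratio scaling and 0.06 at 6 h after quantile normalization, which gives all libraries the same distribution. The 131 most abundant genes had a median of -0.37, with 115 of them below 25 °C and a robust SD of 0.15. Their median at 6 h was -0.69 after median-ratio scaling and -0.03 after quantile normalization, and the group from 6 to 8 changed sign, to -0.26, under median-ratio scaling.

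**Figure D2:**
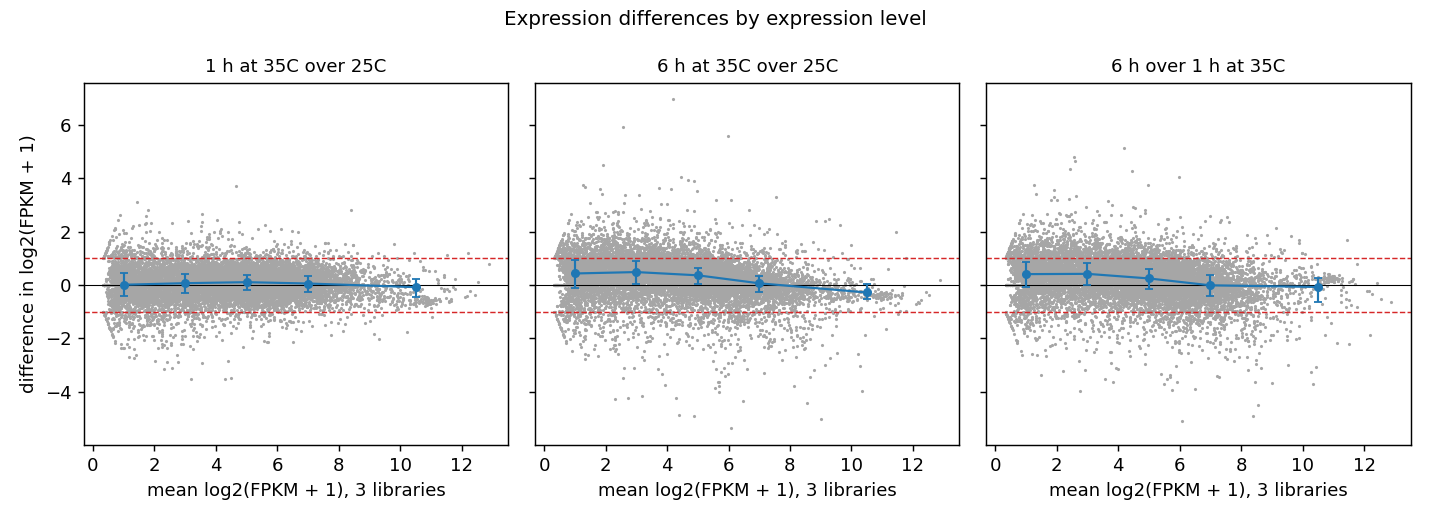
Each grey point is a gene, with its mean log2(FPKM + 1) over the 3 libraries on the horizontal axis and the difference in log2(FPKM + 1) on the vertical axis; blue points are medians of 5 level groups with their quartiles, and dashed lines mark 2-fold. At 6 h over 25 °C the medians go from 0.44 in the weakest group to -0.28 in the strongest, and at 1 h from 0.02 to -0.08.

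The third comparison, of 6 h with 1 h, separates early from late differences. Botdo_15892 and Botdo_15898 again stood furthest above among genes reaching FPKM 10, by 5.13 and 4.82 (log2), and Botdo_13411 furthest below, by -5.09. Botdo_14320, 2.81 above 25 °C at 1 h, was at FPKM 65.7 at 6 h, which lay -4.90 from its 1 h value and -2.09 from its 25 °C value. Between 1 h and 6 h, 1345 genes were at least 2-fold higher and 681 lower, with a median difference of 0.25 over all genes. After median-ratio scaling the numbers were 796 and 999.

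Sorted by their steps, the larger groups were the late ones. The sizes of the late groups, and of the early ones with no further step, were not simulated for unchanged libraries. The robust SD across genes was wider for 6 h over 1 h (0.63) than for 1 h over 25 °C (0.49). No conclusion is therefore drawn from the late groups being larger. As deposited, 1181 genes were within 2-fold at 1 h and stepped up by 6 h. At 6 h, 526 of them (44.5%) were within 2-fold of 25 °C. The group had median FPKM of 5.57 at 25 °C, 4.79 at 1 h and 14.05 at 6 h. Stepping down only after 1 h were 481 genes, and these were stronger, with medians of 77.8, 94.5 and 31.8. Of these, 220 (45.7%) were within 2-fold of 25 °C at 6 h. After median-ratio scaling the late groups held 650 and 783 genes, so the order of their sizes follows the scaling. Early differences with no further 2-fold step after 1 h numbered 260 higher and 250 lower. At 6 h, 112 of the 260 (43.1%) and 110 of the 250 (44.0%) were within 2-fold of 25 °C. Botdo_05614 belonged to the first of these groups, at FPKM 66.0 at 6 h, and Botdo_10019 and Botdo_10048 to the second, at 1.999 and 5.28.

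Higher at 1 h and then lower by a 2-fold step were 175 genes, 148 of which (84.6%) were within 2-fold of 25 °C at 6 h. The mirror group held 142 genes, 128 of them within 2-fold of 25 °C at 6 h. In 100 simulated sets of unchanged libraries with noise of the observed 1 h spread, such groups averaged 135.7 and 134.5 genes, with highest values of 166 and 167. When the 6 h library was simulated with its own observed spread and shift, the averages were 108.4 and 192.9, with ranges of 81 to 134 and 158 to 218. The 175 genes exceeded every set of both simulations, although upper-quartile scaling gave 156, under the highest value of the first, while the 142 lay within the first and below the second. The second simulation gave more higher genes than observed, 497 to 631 at 1 h against 457 and 1524 to 1684 at 6 h against 1406. No conclusion is drawn from the 142 lying below it. The width of noise to assume cannot be measured without replicates.

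Both heat libraries shared 172 genes at least 2-fold higher than 25 °C, which is 37.6% of the 457 higher at 1 h, and 171 at least 2-fold lower, or 41.0% of the 417. Independent lists of these lengths would share 55.5 and 22.5. Both comparisons use the same 25 °C library, and unchanged libraries simulated against it shared 137.6 and 134.6 genes on average, with at most 168 in either direction. That noise has the width of the 1 h differences, without the wider spread and the shift at 6 h, so it is not a like measure for the 6 h lists. With a 6 h library of its own observed spread and shift, simulated sets shared 266.1 higher (226 to 317) and 84.5 lower genes (56 to 105). Those sets held more higher genes than observed: 497 to 631 at 1 h against 457, and 1524 to 1684 at 6 h against 1406. Longer lists share more genes, so this simulation cannot judge the 172 higher ones. As deposited, the 171 lower genes exceeded every set of both simulations, while the 172 higher genes exceeded the first and lay below the second. The simulations were not repeated under other scalings. With median-ratio, upper-quartile and quantile scaling the shared higher genes numbered 129, 136 and 117, under the highest value of the first simulation. Column-total scaling gave 214. The shared lower genes numbered 239, 222 and 243, but 157 with column-total scaling, also under that value. With 1 library at 25 °C the control could not be split, so part of any excess may come from the shared control.

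**Figure D3:**
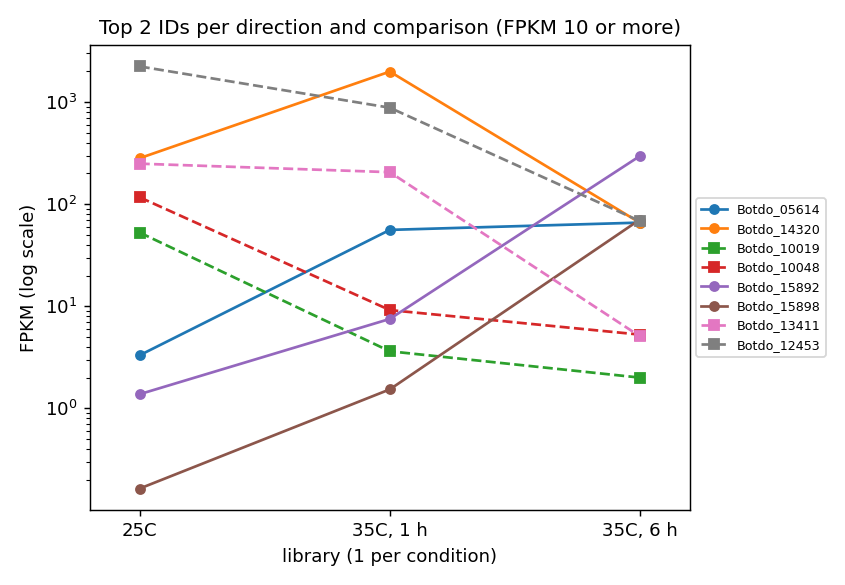
FPKM on a log axis in the 3 libraries for the 8 IDs that had the 2 highest or 2 lowest differences of a comparison among genes reaching FPKM 10. Solid lines with circles mark IDs first named for a higher value and dashed lines with squares those first named for a lower one. Botdo_14320 was named as higher at 1 h over 25 °C and as lower at 6 h over 1 h, and is drawn solid. Botdo_15892 goes from 1.38 at 25 °C to 296.7 at 6 h, Botdo_14320 peaks at 1992 at 1 h, and Botdo_12453 goes from 2238 to 68.3.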

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

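Some genes differed from 25 °C in opposite directions at 1 h and at 6 h, and these differences between the time points were not tested, since each time point has 1 library. At least 2-fold higher at 1 h and at least 2-fold lower at 6 h were 25 genes, where independent lists would share 24.6 and unchanged libraries simulated against a shared control 3.21 on average (at most 9), or 7.75 (2 to 18) when the 6 h library was given its own observed spread and shift. At least 2-fold lower at 1 h and at least 2-fold higher at 6 h were 8 genes, where independent lists would share 50.7 and the simulated libraries 2.86 on average (at most 7), or 16.2 (8 to 27) with its own spread and shift. The first simulation has the width of the 1 h differences and no shift at 6 h. The second gave 1524 to 1684 genes higher at 6 h, more than the 1406 observed. Neither is thus a like measure for these numbers. With a pseudocount of 0.1 these numbers were 44 and 77, with a pseudocount of 5 they were 15 and 4, and at the 4-fold step 1 and 0. Among the named IDs, Botdo_14320 was one of the first kind, at 2.81 above 25 °C at 1 h and at -2.09 from it at 6 h (log2 of FPKM + 1), with FPKM of 282.5, 1992 and 65.7 at 25 °C, 1 h and 6 h.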

How the results depend on the processing

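The 12 differences of the named IDs kept their direction under each pseudocount and under median-ratio and quantile scaling. Their sizes depended on the pseudocount: 8 moved by 0.49 (the robust SD at 1 h) or more with pseudocount 5, and 3 with pseudocount 0.1. With pseudocount 0.1, Botdo_15898 (8.07) passed Botdo_15892 (7.65) at 6 h over 25 °C. Of the values required here, counts of genes are given as higher and lower, for 1 h over 25 °C, 6 h over 25 °C and 6 h over 1 h in turn. With pseudocount 0.1 the first comparison gave 786 and 694. With pseudocount 5 the 3 comparisons gave 165 and 155, 492 and 379, and 486 and 449. At the 4-fold step they gave 36 and 49, 132 and 129, and 112 and 123. A filter at FPKM 5 left 277 lower genes at 1 h. Median-ratio scaling gave 766 and 982 for 6 h over 25 °C and 796 higher for 6 h over 1 h; quantile normalization gave 699 and 941, and 717 higher. Shared by both heat libraries were 433 higher and 260 lower with pseudocount 0.1, 33 and 79 with pseudocount 5, 15 and 19 at the 4-fold step, and 111 higher with the filter at 5. Early differences with no further step numbered 437 higher with pseudocount 0.1, 79 higher and 112 lower with pseudocount 5, 160 and 160 with the filter at 5, and 26 and 40 at the 4-fold step. Genes back down by 6 h numbered 82 with pseudocount 5 and 10 at the 4-fold step. Genes back up numbered 373 with pseudocount 0.1, 28 with pseudocount 5, 94 with the filter at 5 and 7 at the 4-fold step. Late higher genes numbered 454 with pseudocount 5, 105 at the 4-fold step, 650 with median-ratio scaling and 600 with quantile normalization, and late lower genes 111 at the 4-fold step and 783 with median-ratio scaling. A second step the same way was taken by 22 higher and 25 lower genes as deposited, by 108 and 49 with pseudocount 0.1, 4 and 15 with pseudocount 5, and 0 and 2 at the 4-fold step; for higher genes the number was 13 with median-ratio scaling and 11 with quantile normalization. The filter leaves fewer genes and the 4-fold step is a stricter threshold on the same 11571 genes. A larger pseudocount shrinks every log2 difference and a smaller one widens it, by construction. Median-ratio scaling removes the median shift of 0.30 at 6 h over 25 °C, which lowers counts of higher genes and raises those of lower genes. For quantile normalization the cause was not tested. The median difference changed sign at 6 h over 25 °C with median-ratio scaling (-0.0028) and at 1 h over 25 °C with upper-quartile scaling (-0.0075). Median-ratio scaling centres the genes by construction. Upper-quartile scaling divides each library by 1 factor, which lowered 1 h against 25 °C. It moved the median of the 131 most abundant genes from -0.51 to -0.60. The deposited median of all kept genes, 0.06, was small enough to change sign under such a move. The gap between weak and strong genes fell from 0.77 to 0.06 at 6 h over 25 °C under quantile normalization and to -0.059 for 6 h over 1 h, since that method gives all libraries 1 distribution. Of 170 gene counts recomputed under an alternative, 115 stayed within 1.5 times the deposited count, among them all of those with no filter, with upper-quartile or column-total scaling and without rows that share an ID. With a pseudocount of 1, genes under FPKM 1 in all libraries cannot pass 2-fold. The counts past 2-fold without a filter were therefore fixed in advance. Leaving out the 51 rows that share an ID could move the larger counts only little. The alternatives for gene list medians were not run, because no list could be matched to IDs. No paired analysis was possible because each condition has 1 library. The number of fragments is unknown, and with 1 library per condition no count has a replicate error. Of 17 gene counts, the 4-fold step moved 16 by over 1.5 times, pseudocount 5 moved 15 and pseudocount 0.1 moved 8.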

Other observations

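The tests in this part were chosen after their result was seen, except the constant-background test, both tests that remove the level medians from the ID-order patterns at distance 1 and in run length, and the test of shared reads.

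The strongest genes were largely the same in the 3 libraries. Of the 10 with the highest FPKM at 25 °C, 8 were among the 10 highest at 1 h and 6 at 6 h, and 76 genes were in the top 100 of all 3. The 131 genes with mean log2(FPKM + 1) of 10 or more held 32.1% of summed FPKM at 25 °C, 28.0% at 1 h and 26.8% at 6 h. Relative to the median of all genes they lay at -0.57 at 1 h and at -0.67 at 6 h, and at 6 h 44 of them stood below their 1 h value as deposited, but 94 did after median-ratio scaling.

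The longest run of consecutive ID numbers at least 2-fold higher at 6 h than at 25 °C held 9 IDs and included both IDs with the largest positive differences, Botdo_15892 and Botdo_15898. At 25 °C the median FPKM of the 9 was 0.537 and the highest 12.3; at 1 h the median was 1.53 and at 6 h 15.9, with a range from 2.07 to 296.7. At 6 h, 6 of the 9 were at least 4-fold higher, and at 1 h 3 were at least 2-fold higher. The rows of 2 of the 9 lie over 100 rows away from the others in the table. Rows stand largely in blocks of nearby ID numbers, without strict number order inside a block, and what a block stands for is not given. The distance may thus mean that these 2 IDs lie apart from the others. It cannot show whether consecutive numbers mean neighbouring genes.

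At 6 h weakly expressed genes stood higher and strongly expressed ones lower than at 25 °C. One scaling factor moves genes of all levels alike, apart from the pseudocount, so it cannot make the gap between the medians of weak and strong genes. That gap was 0.77 as deposited and 0.81 after median-ratio scaling (0.75 to 0.85 on resampling genes). The scaled gap could hardly have come out otherwise and is no separate test. A constant background would add the same FPKM at every level, but the median difference was 0.735 in genes of mean log2 under 2 and 7.92 in those from 4 to 6, a ratio of 10.8 (9.72 to 11.9). The share of summed FPKM freed by the 100 strongest genes of each library would lift all others by 0.081. With columns scaled to the same total, the like scale, the median shift was 0.40, and as deposited it was 0.30. Summed FPKM is not a number of reads, so the share of reads freed is unknown. RNA quality or preparation of this library and a response to 6 h at 35 °C cannot be told apart with 1 library at 6 h.

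Genes with adjacent ID numbers differed alike between 6 h and 25 °C. Across 9432 pairs of genes, which are not independent replicates, Pearson's r was 0.125, while r in 100 shuffled orders reached at most 0.032. Spearman's rho was 0.095, and it was not computed in shuffled orders. At ID distances of 2 and 3, r was 0.031 and 0.042, above the highest r of the shuffled orders (0.025 at both). There rho was 0.010 and 0.019. At distances of 5, 10 and 50 r lay within the shuffled range, and at 1 h over 25 °C r at distance 1 was 0.084. The level-dependent shift is argued against, as r was 0.125 after the median of each of 20 level bins was removed. Reads shared between overlapping genes stay open: r was -0.0037 in 1497 pairs 16-fold or more apart in level and 0.17 in 5080 pairs within 4-fold, but shared reads would themselves bring levels together, so the unequal pairs exclude nothing, contrary to what was set beforehand. Shared regulation of neighbouring genes may be a further explanation and was not tested.

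For the run of 9 consecutive IDs, a chance order is argued against, because the longest run in 100 shuffled orders was 6. Its length was partly a matter of the shift at 6 h: with level medians removed, 8 of the 9 stayed at least 2-fold higher, but the gap left a longest run of 4, as long as in shuffled orders (4), and the longest run was also 4 under median-ratio and quantile scaling, though it remained 9 under upper-quartile scaling. With a pseudocount of 5, 6 of the 9 were at least 2-fold higher. The size of the differences is not accounted for by that shift, since the highest median over any of 2992 windows of 9 consecutive IDs was 2.31 (log2) after the medians were removed, at a window 1 ID away from the run's start, against at most 1.201 in shuffled orders. Reads spilling over from the strongest ID, Botdo_15892, stay open: over the 7 IDs not named the differences fell with ID distance from it (Spearman's rho -0.68), and Botdo_15898, which lay 2.32 above the 5 IDs between, was chosen for its difference. That these IDs form a group of genes switched on together late in heat is a hypothesis from 1 library, which gene names, coordinates and replicate libraries would test.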
